A study of Mus musculus with 10 samples.

How the data were processed

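Total RNA of sorted lung ILC2 from mice given papain was sequenced as 10 libraries, 5 WT and 5 c-Maf KO, made with a strand-specific total RNA kit, per the labels' protocols. The labels also state that the mice were cohoused littermates. The deposited values are whole-number read counts per gene, not normalized, with 1 column per library. STAR 2.6.0c, SAMtools 1.8 and HTSeq 0.9.1 are named in the submitters' processing notes, with genome build GRCm38; the annotation release, the strand setting and the filters are not given in the sources used here. Groups were taken from the genotype in the labels. Libraries are numbered in the order of deposit, and no number pairs a WT with a KO library.

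The table lists 54838 gene identifiers, of which 54809 matched the GENCODE annotation of GRCm38 used for symbols, positions and spans. Of 480 protein-coding genes whose exons lie inside introns of a gene on the opposite strand, 98.8% were at 0 in every library, and of 192 inside a gene on the same strand 98.4%, against 35.1% of 14131 genes without overlap. Genes that overlap another gene, such as Tnfrsf18, Xist and Tcf7, were therefore treated as not measured or as uncertain. A total of 19014 genes had any count.

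The main test was edgeR 4.0.16 (R 4.3.3): genes were kept by filterByExpr with its minimum of 10 counts, libraries were scaled by TMM, and the quasi-likelihood test compared KO with WT. Benjamini-Hochberg adjustment covered the 7490 genes kept, at a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the test's F. TMM factors were 1.462 to 1.908 in WT and 0.1803 to 0.9276 in KO, so the scaling itself separates the groups. Levels are TMM-scaled CPM, as mean ± SD of 5 libraries, unless library size is named. Exact two-sided permutation tests of log2(CPM + 1) were added for Maf and the genes named whatever their result. A gene was called missing in a library with at most 3 counts. Where all KO libraries were at 0, a fold is a lower bound against 3 counts over the KO group. Where a group held 1 to 3 counts in total, the ratio of the counts per scaled library size is given with its exact 95% interval. Counts of reads without molecular identifiers are not independent molecules, so bounds and intervals cover counting error only. For each named gene, the 200 genes nearest in WT level show how often genes of that level were missing from as many KO libraries.

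Before the data were examined, 35 gene lists were fixed, of ILC2 identity and effector genes, related immune programs, MAF partners, stress, cell cycle, metabolism, RNA classes and markers of other cell types. They were tested with camera (limma 3.58.1, preset correlation 0.01) where at least 3 members were tested, and with camera at an estimated correlation and fry. Named genes were also fixed by rule: Maf; of genes that passed, with a mean of at least 5 CPM and a symbol that is not a clone or model name, the 12 largest rises and 12 largest falls; up to 4 members by smallest p of each list described; and 22 ILC2 and MAF family genes whatever their result. Some genes that the rule names are not reported here. Genes named outside the rule were chosen after their values were seen; this holds for Il17rb, Gfi1, H2-Aa and H2-Eb1, and in the closing section for those singled out by the model of missing genes and for the loci CT010467.1 and Gphn.

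Alternatives fixed before the data were examined were RLE size factors, library size alone, DESeq2 1.42.0, voom with and without sample quality weights, a robust fit, other filters and thresholds, leaving out mitochondrial, ribosomal and small structural RNA genes, 1 surrogate variable (sva 3.50.0), guessed blocks of related animals, and leaving out each library in turn. Added after seeing the data were thinning to the smallest total, leaving out globin and mitochondrial genes, genes of at least 100 CPM, leaving out KO libraries 1 and 5, and the permutation tests.

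The procedure was tested on data simulated from the real means, library sizes and separate dispersions of the groups (median 0.482 in WT and 6.69 in KO). Over 7190 genes, the test recovered 6% of 50 genes planted at 4-fold, 6% at 16-fold, 28% at 64-fold and 52% at 256-fold, and called 2.93% of 6993 unchanged genes. These 205 false calls, 205 lower and 0 higher, were 81.7% of the 251 calls, so the adjusted threshold of 0.05 does not hold its rate for lower calls when the groups differ in spread. In 20 further draws without any change, 115 to 214 genes were called lower and 0 higher, a median of 7.57% of the count of lower calls in the real data, though these draws lost fewer genes than the KO libraries did (54.2% against 73.1% of tested genes at 20 to 50 CPM). At this spread, most changes under 64-fold stay undetected, and a gene that did not pass is not shown to be unchanged. A planted list of 20 genes at 16-fold was found by camera (adjusted p = 9.07e-07) with 0 of 34 other lists called. The simulated genes were independent and these lists random, so the false rate for lists of correlated genes was not tested. The model of missing genes recovered 18 of 20 planted genes of at least 200 CPM with 0 false calls among 4538 genes.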

Results

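Group 2 innate lymphoid cells (ILC2) are tissue lymphocytes that lack antigen receptors and secrete type 2 cytokines. Lung ILC2 of C57BL/6 mice, either wild type (WT) or lacking the transcription factor c-Maf (KO), were profiled by total RNA sequencing after lung inflammation raised with papain, a protease allergen. The cells had been sorted as lineage-negative and CD90.2-positive, with or without ST2 and KLRG1 on their surface. There were 5 WT and 5 KO libraries, numbered here in the order of deposit, and the numbers pair nothing. Each library carries its own number in the labels, which do not say in words that each came from a separate mouse, so p-values measure the spread between these libraries. The number of every KO library is above that of every WT library, so the groups differ in this order as well as in genotype. The comparison asks which transcripts of lung ILC2 differ when c-Maf is missing.

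The WT libraries held 21400938 to 24489987 counts each and the KO libraries 3620002 to 9867580. At least 1 count was found for 11880 ± 803 genes in WT and for 6268 ± 1492 genes in KO (mean ± SD, n = 5 each). Across genes, the WT libraries correlated with each other at a Spearman rho of 0.826 to 0.873, and the KO libraries at 0.448 to 0.571, which is within the range of 0.424 to 0.601 between the groups. In KO library 1, 100 genes took 93.43% of the counts and the 4 globin genes took 19%. The other KO libraries held 49.1 to 57.85% in 100 genes and the WT libraries 48.82 to 61.01%. No pair of libraries within a group was alike within sampling noise.

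**Figure D1:**
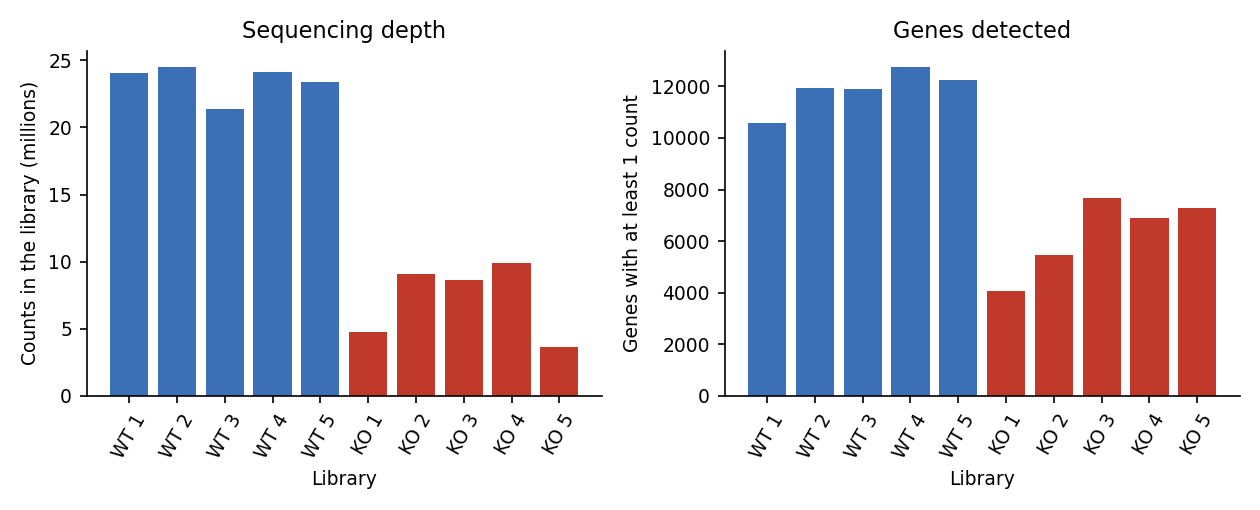
Counts per library (left, axis in units of 1e6) and genes with at least 1 count (right), 1 bar per library, WT in blue and KO in red. The KO libraries lie between 3620002 and 9867580 counts and between 4052 and 7660 genes, all below the WT libraries, which start at 21400938 counts and 10577 genes.

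Maf, the targeted gene (ENSMUSG00000055435, GRCm38 chromosome 8, 115682942 to 115707794, minus strand, protein coding), was present in every WT library and in 1 of the 5 KO libraries. Its counts were 3252, 3832, 1412, 1696 and 2727 in WT libraries 1 to 5, and 0, 0, 0, 108 and 0 in KO libraries 1 to 5. This corresponds to 64.2 ± 24.9 CPM (counts scaled to a common library size of 1e6) in WT and 3.08 ± 6.89 CPM in KO (SD, n = 5 each, TMM-scaled). The level was below every WT library in 5 of 5 KO libraries. An exact two-sided permutation test of log2(CPM + 1) gave p = 0.00794, the smallest that 5 against 5 libraries allow, and an adjusted p of 0.0582 over the 22 genes tested in that way. The edgeR log2 fold change was −4.34 (SE 2.06), with an adjusted p of 0.141 over all genes, so the difference missed the threshold of 0.05 in that test. KO library 4 decided this value: without it the log2 fold change was −13.61, fitted against KO libraries that are all at 0, with an adjusted p of 0.00525. Many other genes were missing from KO libraries too: of 200 genes with the WT levels nearest to that of Maf, 10.5% had at most 3 counts in at least 4 KO libraries. At exactly 0 counts this was rarer: 4 of the 719 genes at 100 to 200 CPM in WT (per library size, where Maf stood at 109 CPM) were at 0 in at least 4 KO libraries. The counts cover the whole gene, and the sources used here do not say which part of Maf was deleted.

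Of the type 2 cytokine genes, Il4 passed the edgeR test and Il13 and Il5 did not. Il4, the cytokine that drives IgE class switching, fell from 12.3 ± 8.44 CPM to 3 counts over all 5 KO libraries (adjusted p = 0.00232), a ratio of 101 (95% counting interval 34.4 to 488). However, 33% of genes of like WT level were missing as often, and the exact permutation test gave p = 0.00794, with an adjusted p of 0.0582 that missed the threshold. Il13, a driver of mucus production, stood at 869 ± 232 CPM in WT and 193 ± 209 CPM in KO, with a log2 fold change of −2.17 (SE 1.26) and an edgeR adjusted p of 0.241. Its exact permutation p was 0.0159 (adjusted p = 0.0874). Il5, the growth factor of eosinophils, stood at 92.7 ± 15.2 and 32.9 ± 66.2 CPM, was below every WT library in 4 of 5 KO libraries and above every one in KO library 5, and had an edgeR adjusted p of 0.585. Without that library its log2 fold change was −4.72 and the adjusted p 0.0403. With voom in place of edgeR, Il5 and Il13 passed, at log2 fold changes of −4.5 and −3.655. The median tested gene stood at −3.58 with voom, a median that includes many weak genes missing from KO libraries. Whether these passes show a fall beyond that of genes of like level was not tested. Over all alternatives apart from leaving out single libraries, the adjusted p ran from 0.0294 to 0.826 for Il5 and from 0.0271 to 0.419 for Il13. Areg, an epithelial growth factor made by ILC2, stood at 261 ± 78.1 and 351 ± 560 CPM (edgeR adjusted p = 0.854), and Csf2 at 2.66 ± 1.87 and 0.912 ± 2.04 CPM (edgeR adjusted p = 0.484). Without KO library 4, which alone held Csf2 counts, the adjusted p of Csf2 was 0.0103. Il9 and Il10 were too weak for the edgeR test: Il9 had 327 WT counts, nearly all in WT library 1, and Il10 had 499, in 3 WT libraries, against 0 in KO. Their exact permutation p-values were 0.444 and 0.167 (adjusted p = 0.595 and 0.306). Of the 14 tested members of the list of type 2 effector molecules, 1 fell, 0 rose and 13 did not pass, and their median log2 fold change was 0.55 (camera, adjusted p = 0.453). That median was −1.65 with library size alone and −3.23 with voom, and fry, which does not compare with other genes, pointed downward (adjusted p = 9.21e-05). Il6 stood at 6.02 ± 7.28 and 277 ± 514 CPM (edgeR adjusted p = 0.0788; 0.0363 and 0.0266 without KO library 1 or 4) and the chemokine gene Ccl1 at 31.4 ± 17.6 and 285 ± 332 CPM (edgeR adjusted p = 0.177; 0.0361 without KO library 1). Il6 and Ccl1 passed with DESeq2 as well (adjusted p = 0.00517 and 0.0264) and with 1 surrogate variable, but not over all alternatives (up to 0.471 and 0.747).

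Of the 15 tested members of the ILC2 identity list, 7 had over 3 counts in every KO library, while Nmur1 had at most 3 in 5 of them and Il17rb and Gfi1 in 4. A single KO library decided the last 2. Il17rb had a log2 fold change of −0.19, and −5.69 without KO library 2 (edgeR adjusted p = 0.0314). Gfi1 had 3.09, and −5.19 without KO library 3 (edgeR adjusted p = 0.017). Il1rl1, which encodes the IL-33 receptor ST2, stood at 532 ± 55.9 CPM in WT and 2360 ± 2270 CPM in KO (log2 fold change 2.15, SE 0.951, edgeR adjusted p = 0.112). Il7r stood at 554 ± 149 and 1080 ± 448 CPM, Gata3, the main transcription factor of type 2 lymphocytes, at 241 ± 79.1 and 595 ± 772 CPM, and Rora, a transcription factor that ILC2 need to develop, at 1040 ± 299 and 4280 ± 4140 CPM. Their edgeR adjusted p-values were 0.506, 0.463 and 0.141, and without KO library 1 those of Il1rl1 and Rora passed, at 0.0139 and 0.00874. Without KO library 3 that of Il1rl1 was 0.0424. Il2ra, Icos, Klrg1 and Thy1 did not pass either, with edgeR adjusted p-values of 0.302, 0.647, 0.915 and 0.122. Without KO library 1 that of Thy1 was 0.0181. Il1rl1, Rora and Thy1 also passed with DESeq2 (adjusted p = 0.00828, 0.032 and 0.0393) and with 1 surrogate variable, and over the alternatives apart from single libraries their adjusted p reached 0.601, 0.566 and 0.901. Il2ra passed without KO libraries 1 and 5 (adjusted p = 0.016) and Klrg1 with a random effect of guessed blocks (0.0329). Klrg1, an inhibitory receptor of mature ILC2, stood at 193 ± 53.8 and 156 ± 281 CPM and had 1 and 2 counts in KO libraries 1 and 3. In that list 1 member fell and 14 did not pass: Nmur1, the receptor through which neuromedin U activates ILC2, had 6169 counts in WT and 5 in KO (28.9 ± 15.4 and 0.26 ± 0.364 CPM, log2 fold change −6.78, SE 1.70, edgeR adjusted p = 0.00481). Of all tested genes, 27.1% were lower in KO. At 20 to 50 CPM in WT (per library size) 523 of 2070 genes were missing from all 5 KO libraries, and at 50 to 100 CPM 81 of 1169. The sign of some log2 fold changes in the ILC2 identity list depends on the scaling: with library size alone, Gata3, Il7r and Icos had −0.12, −0.40 and −1.52, and with RLE size factors Klrg1 had 0.58 and Il17rb 0.19.

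**Figure D2:**
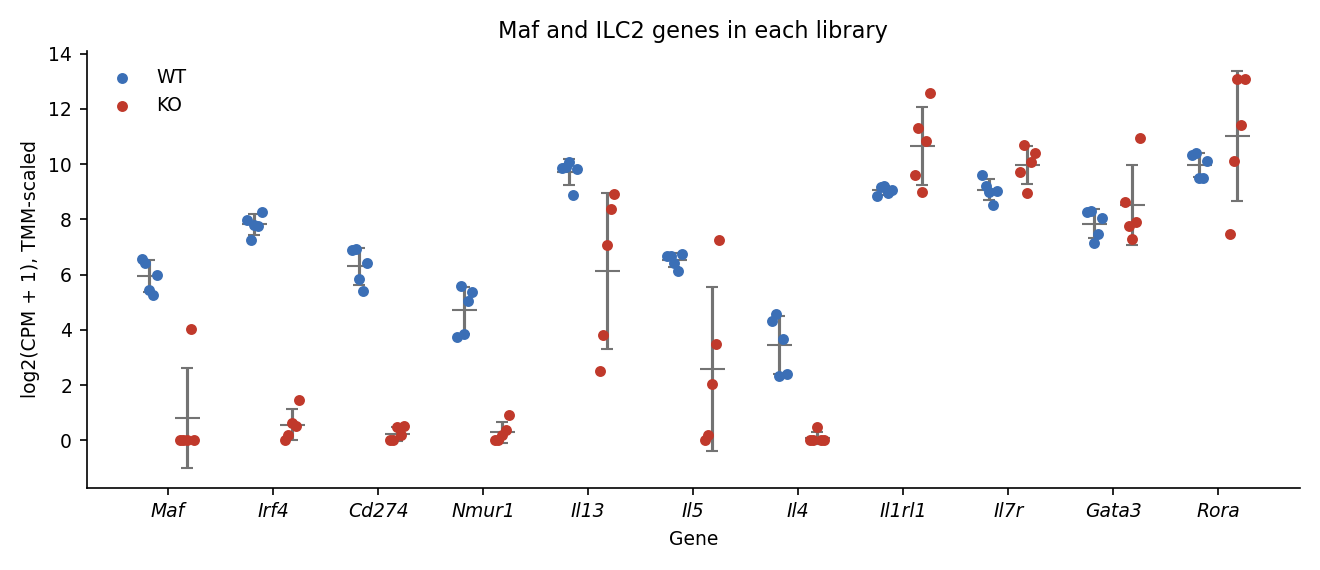
TMM-scaled log2(CPM + 1) of 11 genes in each WT (blue) and KO (red) library, with the mean and SD of 5 libraries as a dash and bar. Maf, Irf4, Cd274, Nmur1 and Il4 lie below every WT library in 5 of 5 KO libraries. Il1rl1 lies above every WT library in 4 of 5, a position that rests on the scaling.

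Immune regulators were among the genes that fell, as were 27.1% of all tested genes. The lists named in this paragraph were not shown to fall more than other genes. Irf4, a transcription factor of lymphocyte activation, had 46393 counts in WT and 12 in KO (231 ± 58 and 0.576 ± 0.693 CPM, log2 fold change −8.61, SE 1.82, edgeR adjusted p = 0.00168). It had at most 3 counts in 3 of 5 KO libraries. Of 200 genes of like WT level, 1.5% had at most 3 counts in at least as many. Of the 12 tested members of the IL-10 and inhibitory receptor list, 4 fell and 8 did not pass (camera, adjusted p = 0.774). Cd274, which encodes the checkpoint ligand PD-L1, had 16995 counts in WT and 5 in KO (log2 fold change −8.61, SE 1.97, edgeR adjusted p = 0.00246), and 0% of its 200 matched genes were missing as often. The model of missing genes, from WT level and genomic span, expected it to be missing in 1.93 KO libraries. Its exact tail p of 0.00525 in that model does not pass the adjustment over all genes. Havcr2 (TIM-3) had 1812 and 0 counts, at least 74-fold lower in KO, and 45.5% of its matched genes were missing as often. Tigit had 3178 and 2 counts, and Btla 892 and 5. The call of Btla (edgeR adjusted p = 0.0147) was lost with DESeq2 and voom, among other settings (adjusted p up to 0.0998). Among receptors for alarmins, cytokines, lipids and neuropeptides, 2 of 27 tested members fell, Nmur1 and Il1rap, the co-receptor chain of ST2 (1647 and 13 counts, edgeR adjusted p = 0.018). Of the MAF family and its partner factors, 3 of 16 tested members fell, 1 rose and 12 did not pass (camera, adjusted p = 0.994). Mafk, a small MAF protein, had 2692 and 1 counts (ratio 321, 95% counting interval 57.6 to 12700). Its exact permutation p was 0.00794, with an adjusted p of 0.0582 that missed the threshold. Batf, an AP-1 factor that pairs with IRF4, had 4694 and 0 counts (at least 190-fold lower). Sox5 rose, from 453 to 6907 counts, 6837 of them in KO library 3, without which its edgeR adjusted p was 0.234. Bach2, Maff and Mafg did not pass (edgeR adjusted p = 0.488, 0.715 and 0.953). Without KO library 2, which alone held Mafg counts, Mafg stood at −10.66 and passed (adjusted p = 0.00598). Tcf7 was too weak for the edgeR test (exact permutation p = 0.444, adjusted p = 0.595). Tbx21 was listed at 0 in every library, so it may not have been measured. Tcf7 lies largely within another annotated gene, so its counts are uncertain.

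Over all genes, 7490 were tested with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05; 2027 were lower in KO and 112 higher. Of the 2027, 1647 had at most 3 counts in all 5 KO libraries, 323 in 4 of them and 0 were above 3 counts in every KO library. The share of missing genes depended on the WT level: at 20 to 50 CPM in WT, from 64.1 to 89.3% of 2070 genes had at most 3 counts in a KO library, and at over 1000 CPM, from 0 to 2.99% of 67 genes. The share of lower calls was 94.8%, and with edgeR it was 90.4% with RLE size factors and 97.9% with library size alone. With DESeq2, which differs in test, size factors and filter (11789 genes), 1483 genes were higher and 2588 lower (63.6%). With no filter on low counts in edgeR 2345 were higher and 3024 lower (56.3%). The main filter asks for enough counts in at least 5 libraries. A gene absent from WT was thus tested only if it was seen in every KO library, which favors lower calls. Leaving out KO library 2 gave 318 higher and 3171 lower calls, and the other 4 KO libraries moved the count of higher calls by over 1.5 times as well, to between 215 and 333. The count of lower calls then ranged from 3021 to 3350, with 8812 to 8953 genes tested against 7490 in the main test. The median log2 fold change of all tested genes was −0.467. Library size alone shifted that median by −1.30, RLE size factors by 0.56 and voom by −3.11. With DESeq2 the median was 1.24, but over all genes with any count, so it does not measure a shift of the same genes.

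**Figure D3:**
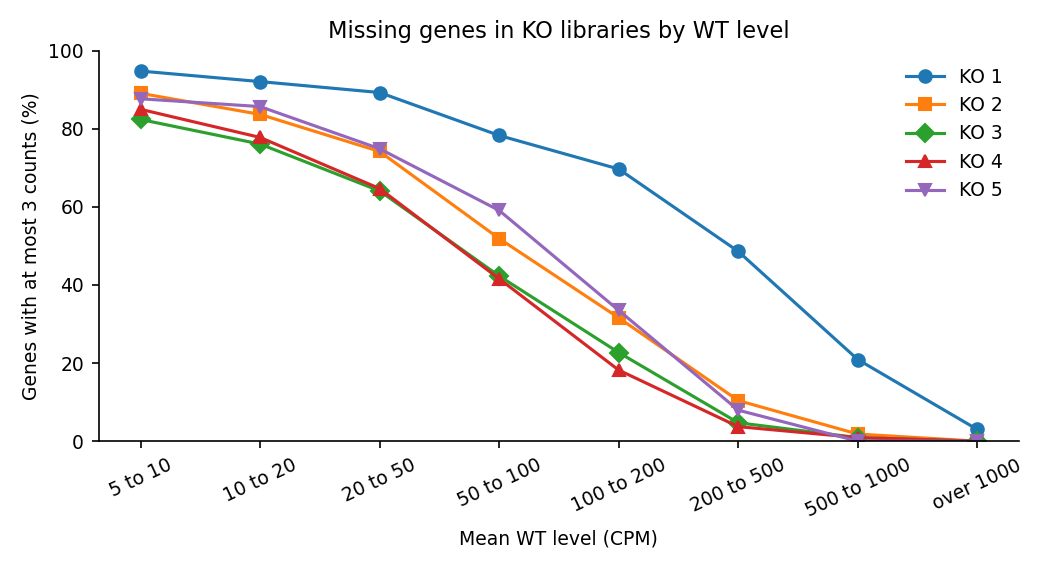
Share of genes with at most 3 counts in each KO library, in percent, by the mean WT level of the gene in CPM per library size. In each of the 5 KO libraries the share falls with the WT level, and KO library 1 has the highest share at each level, from 94.8% at 5 to 10 CPM to 2.99% above 1000 CPM.

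The 12 largest falls among genes of at least 5 CPM were all of genes at 0 in every KO library. The first was H2-Ab1 (ENSMUSG00000073421), a chain of the MHC class II molecule I-A, with 12507 WT counts, 62.9 ± 9.12 CPM, at least 505-fold lower in KO (edgeR adjusted p = 0.00182). Other MHC class II genes did not pass with edgeR: its partner chain H2-Aa had 1168 KO counts, H2-Eb1 1610 and Cd74 26170, with log2 fold changes of −1.11, 0.757 and 1.22 (edgeR adjusted p = 0.69, 0.829 and 0.577), and with library size alone H2-Eb1 stood at −0.51 and Cd74 at −0.013. H2-Eb1 had at most 3 counts in 4 of 5 KO libraries. Without KO library 4 it stood at −7.54 and passed (edgeR adjusted p = 0.0106), while Cd74 stood at −0.14. H2-Eb1 also passed as lower in an alternative that kept all libraries. H2-Aa passed with voom at a log2 fold change of −4.582, where the median tested gene stood at −3.58. Over its alternatives apart from single libraries, the adjusted p of H2-Aa ran from 0.0284 to 0.912. Next came Dusp4, a phosphatase that turns off MAP kinases (at least 331-fold lower), Atp6v0d1, a subunit of the vacuolar proton pump (313-fold), and Taf1, a subunit of TFIID (278-fold), followed by Pcyt1a, Cpsf2, Vps35, Smarcb1, Mxd4, Bmpr1a, Csnk2b and Tmem170b, at least 275-fold to at least 224-fold lower. These bounds are set against a floor of 3 counts over the KO group, which is 0.124 CPM, and cover counting error only. Of genes of like WT level, 3.5% for H2-Ab1 and from 8 to 18% for the others were missing from as many KO libraries.

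The 12 largest rises were led by 4 globin genes, the genes of red blood cells. Hba-a1, Hba-a2, Hbb-bs and Hbb-bt together gave 902039 counts in KO library 1, from 387 to 6475 in the other KO libraries and from 34 to 215 in the WT libraries. Hba-a1, Hba-a2 and Hbb-bs were above every WT library in 5 of 5 KO libraries (edgeR adjusted p = 0.00163 each). Hba-a1 and Hba-a2 are near-identical copies, as are Hbb-bs and Hbb-bt, so the split of counts within each pair is uncertain. Of the 8 erythroid markers 5 were tested and 5 rose, the globins and Bpgm. The next were genes that span long stretches of the genome: Sox6, Kif26b, Tenm2, Ptprt, Dpyd, Opcml and Lrp1b. Sox6 had 3 counts in WT and 5154 in KO (ratio 14400, 95% counting interval 4920 to 69800, edgeR adjusted p = 0.00163), and was above every WT library in 5 of 5 KO libraries. Most counts of the others came from 1 or 2 KO libraries: KO library 3 gave 11382 of the 12615 KO counts of Lrp1b, 6598 of the 6923 of Opcml and 3263 of the 3430 of Kif26b. KO library 5 gave 1249 of the 1489 of Tenm2 and KO library 4 gave 1029 of the 1396 of Dpyd, while Ptprt had 4056 and 3343 counts in KO libraries 2 and 5. The 12th gene, Otud1, had 7663 of its 8164 KO counts in KO library 1, without which it did not pass (edgeR adjusted p = 0.0781). Of the 112 genes that rose, 64.3% spanned over 100 kb, against 16.6% of all tested genes, and their median span was 341 kb against 31.4 kb. The same relation held for 7544 protein-coding genes that overlap no other gene and had under 25 WT counts: at least 20 counts over the 5 KO libraries were found for 0.318% of the shortest octile and 45.8% of the longest. WT counts in these genes, capped by the choice, rose with span as well (Spearman rho 0.36 across genes, 0.55 for KO counts).

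**Figure D4:**
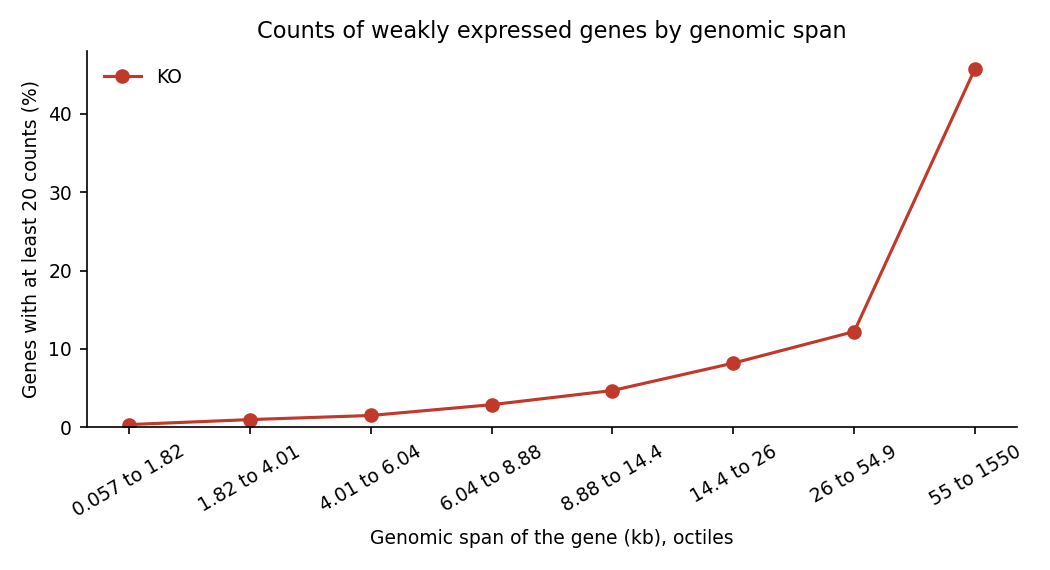
Share of genes with at least 20 counts summed over the 5 KO libraries, in percent, by octile of genomic span in kb, for 7544 protein-coding genes with under 25 WT counts (943 per octile). The share rises from 0.318% in the shortest octile to 45.8% in the longest.

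Of all tested genes, 27.1% were lower, and the lists of metabolism, cell division and survival genes did not pass when set against the other genes by camera (adjusted p of 0.159 or more). Of the nuclear genes of oxidative phosphorylation, 12 of 29 tested members fell and 17 did not pass: Cox5b, Ndufa7, Ndufs5 and Uqcrb were at 0 in all KO libraries, at least 64.2-fold, 75.3-fold, 29-fold and 26-fold lower. Of glycolysis and hypoxia genes 7 of 18 fell and 11 did not pass. Tpi1 and Pgam1 were at least 71.5-fold and 51.7-fold lower, and the hexokinase gene Hk2 and the lactate exporter gene Slc16a3 had 2645 and 653 counts in WT against 1 each in KO. For fatty acid uptake, storage and oxidation 3 of 13 fell, Acadm, Acadvl and the desaturase gene Scd2 (778, 531 and 3227 counts in WT against 0, 0 and 1). For sterol synthesis 3 of 15 fell, among them Sqle, the squalene epoxidase (5290 and 1 counts), and Stard4 (3914 and 2). Of the genes of mitosis and DNA replication 5 of 17 fell, with Mcm4 and Ccnb2 at least 152-fold and 36.3-fold lower, Rrm1 at 2323 and 1 counts and Cenpf at 1427 and 2. Replication-dependent histone genes fell in 2 of 5, Hist1h1d (1172 and 3 counts) and Hist1h2bc (1080 and 6). Of apoptosis and survival genes 7 of 14 fell, including Trp53, which encodes p53 (12535 and 3 counts, ratio 499, 95% counting interval 171 to 2420, edgeR adjusted p = 0.00622), Bid (at least 32.1-fold lower) and Cdkn1b (3152 and 1 counts). For Mcm4, 17% of matched genes were missing from as many KO libraries, for Trp53 3.5%, and for Acadvl 68.5%. At most 3 counts in all 5 KO libraries was common at low WT levels (CPM per library size). It held for 898 of 1529 genes at 5 to 10 CPM and for 725 of 1635 at 10 to 20 CPM.

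Of the ILC1 and T-bet program 2 of 9 tested members fell, among them Il12rb1, a chain of the IL-12 receptor (1929 and 0 counts, at least 77-fold lower). Of the ILC3 program 2 of 9 fell, Batf and Ltb (2129 and 1 counts). Of type I interferon response genes 3 of 17 fell, among them Cmpk2 (at least 50-fold lower) and Xaf1 (1100 and 1 counts). For tissue residency and migration 1 of 17 fell, Ccr7, which guides cells to lymph nodes (1121 and 5 counts, edgeR adjusted p = 0.045). Its call was lost without WT library 2 or 5 or any of KO libraries 1 to 4, with adjusted p-values up to 0.127. Ccr7 and Bcl6 (5195 and 29 counts, edgeR adjusted p = 0.0225) were the 2 of 13 memory and stem-like genes that fell. Among immediate-early and dissociation genes 1 of 23 rose and 1 fell: Atf3 stood at 31.8 ± 17.5 and 526 ± 351 CPM (edgeR adjusted p = 0.0486, lost without any 1 of the 5 WT libraries, at up to 0.125), and Dnajb1 was at least 68.5-fold lower. Of unfolded protein and amino acid stress genes 1 of 16 fell, Xbp1 (2767 and 0 counts, at least 107-fold lower), and 0 of 18 NF-kB target genes passed, 0 at an adjustment over the list alone. Adjusted over the list alone, the counts that fell were 1 of 27 for the receptors, 0 of 17 for residency, 0 of 13 for memory genes, and 2 of 15 for sterol synthesis, Atf3 no longer passed, and the other lists kept the counts given.

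As groups set against all other tested genes, 8 of the 27 lists with at least 3 tested members passed (camera with a preset correlation of 0.01, adjusted p over the 27), each shifted upward in KO. They were ribosomal proteins (adjusted p = 3.61e-08, 27 tested members), erythroid markers (1.7e-05), mitochondrially encoded genes (0.000782), ILC2 identity (0.0116), receptors (0.0203), immediate-early genes (0.0203), memory and stem-like genes (0.0211) and small structural RNAs (0.0296). None of these 8 passed with an estimated correlation, where the smallest adjusted p was 0.233. No tested member of the ribosomal protein list or of the mitochondrially encoded list passed alone with edgeR: Rps14 stood at 127 ± 125 and 583 ± 481 CPM, Rpl27 at 111 ± 85.8 and 350 ± 248 CPM, and mt-Nd2 at 258 ± 93.1 and 887 ± 458 CPM (edgeR adjusted p = 0.225, 0.369 and 0.233). With DESeq2 Rps14, Rpl27 and mt-Nd2 passed (adjusted p = 0.0198, 0.0334 and 0.0091). In the list of small structural RNAs 1 of 4 tested members rose, Lars2, placed there because its locus collects ribosomal RNA reads (edgeR adjusted p = 0.00183). The members' median log2 fold change was 0.82 for ribosomal proteins, 0.97 for ILC2 identity, 0.22 for receptors and 1.05 for mitochondrially encoded genes, and scaled by library size alone it was −0.53, −0.40, −1.10 and −0.65. These directions are relative to the other tested genes, many of which were missing from KO libraries. In the same fit, the 1371 genes of at least 100 CPM had a median log2 fold change of 1.89. That limit removes genes absent from KO. The upward shift of a list therefore cannot be told apart from the level of its members. fry, which asks whether the members move one way without comparing them with other genes, passed 18 of the 27 lists at an adjusted p of 0.05, and pointed downward for ILC2 identity (limma fry, adjusted p = 0.339), receptors (0.00239), memory genes (0.333) and immediate-early genes (0.144), opposite to camera.

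Markers of other cell types were mostly not tested, since they were weak or listed at 0 in every library. Of T cell markers 0 of 7 passed with edgeR; Trbc2, the T cell receptor beta constant gene, stood at 106 ± 42.4 and 44.7 ± 60.7 CPM (edgeR adjusted p = 0.633). Trbc2 passed with voom (adjusted p = 0.0241) and with the random effect (0.0103). Its log2 fold change with voom was −4.755, where the median tested gene stood at −3.58. The downward direction of fry for the T cell list (limma fry, adjusted p = 0.00488) means that a fall of T cell transcripts is not excluded. Of macrophage and monocyte markers 2 of 4 fell, Lyz2 and Chil3. Both were uneven among the WT libraries, with 31 to 11144 counts for Lyz2 and 9 to 58165 for Chil3, against at most 3 and 9 in a KO library. Of dendritic cell markers 2 of 6 fell, H2-Ab1 and Xcr1 (at least 29.1-fold lower). Of B and plasma cell, mast cell and basophil, epithelial and endothelial markers 1, 1, 2 and 2 were tested and 0 passed. No NK cell, neutrophil, eosinophil, or fibroblast and mural marker was tested.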

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

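A library was singled out where its gap to the nearest library of its group, divided by the range of the group, passed the Dixon limit of 0.71 for 5 libraries; 16 of 82 groups of values passed, where chance gives about 4.1. Of the tests weighed here, the bottleneck matched on genes above 3 counts, the test of independent loss, the simulation of unequal spread, the number of genes at an equal total, and those on gene span, on globin ratios and on Maf were chosen after the results were seen.

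KO library 1 stood apart from the other KO libraries in the share of counts in 100 genes (gap 0.803 of the range) and in the globin share (0.997), and in Hba-a2 (0.754), Hba-a1 (0.758) and Hbb-bs (0.784). Maf was at 15.4 CPM in KO library 4 and at 0 in the other KO libraries (gap 1). In the same way, KO library 3 alone held Il4 (0.411 CPM, gap 1) and Mafk (0.137 CPM, gap 1), KO library 4 alone held Csf2 (4.56 CPM, gap 1), and KO library 2 alone held Mafg (46.5 CPM, gap 1). Bach2 was lowest in KO library 3, at 0.822 CPM against 119 to 550 CPM in the others (gap 0.733). Among the WT libraries, WT library 4 had the lowest Il13 (469 CPM, others 908 to 1070, gap 0.801), and WT library 1 the lowest Areg (125 CPM, others 281 to 325, gap 0.847) and Otud1 (0.0286 CPM, others 0.66 to 0.973, gap 0.735). Kif26b and Dpyd had a single WT count each, in WT library 5 (gap 1).

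Counts on 4 Y-linked genes (Ddx3y, Uty, Kdm5d and Eif2s3y), which the comparison does not use, were 2 in each WT library and 12, 0, 3272, 1857 and 104 in KO libraries 1 to 5. The labels give no sex. KO libraries 3 and 4 held these counts in 3 different genes each, and in KO library 5 nearly all, 100 of 104, were on Uty. A sex term was planned for the case that both sexes are in both groups and was not fitted, so an effect of sex, on the comparison of KO with WT or among the KO libraries, was not tested and stays open. By these counts no WT library resembled KO libraries 3 and 4, so sex may be partly confounded with genotype.

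The first pattern is the 2027 lower calls against 112 higher ones: of 100 of the 126 splits of the 10 libraries, 1 split, the real one, gave as many lower calls, and the highest other count was 40, so chance is excluded for the split, though depth, the order of the label numbers and genotype split the libraries alike. Splits that mix the groups do not keep their unequal spread. Data simulated with that spread and no change gave a median of 153.5 lower calls (20 draws), so some lower calls are to be expected from spread alone. The balance of the calls also rests on the filter on low counts, without which 2345 genes were higher and 3024 lower. Passing WT libraries through a simulated loss of molecules that leaves as many detected genes as each KO library gave a median of 0 lower calls, but that test was void, because it removed 19.5% of genes at 20 to 50 CPM where the real KO libraries lacked 73.4%; matched on genes above 3 counts, with 57.3% removed, it gave a median of 869.5 lower and at most 0 higher calls in 20 draws. Of 4538 genes of at least 20 CPM in WT, 615 were missing in all 5 KO libraries where independent loss in each library predicts 527 ± 20.1 (SD), so loss set by WT level and span alone does not account for all of them; 465 were also missing in none where 413 were expected. Thinning all libraries to 3620002 counts left 1274 lower calls and 9040 to 11225 genes detected in WT against 3621 to 7273 in KO, which excludes depth as the whole cause but not as a part of it, so random loss of RNA before sequencing and an effect of c-Maf cannot be told apart for these genes: the low-yield libraries are the KO libraries.

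The second pattern is the 112 higher calls, which 1 of 100 splits, the real one, reached (highest other 40), and the simulation of unequal spread, which lost fewer genes than the real KO libraries, gave a median of 0. Leaving out globin and mitochondrial genes before scaling left 111 higher calls but moved the median log2 fold change by 0.00426, so it tests nothing about them. The median span of the 112 genes was 341 kb against 31.4 kb for all tested genes (range of the central 95% of random lists matched on level 29.5 to 54.6 kb), which fits reads from whole gene bodies, such as genomic DNA or unspliced RNA, as a candidate explanation for most of the list. The globin genes are short and need another source. Carry-over of reads from KO library 1 predicts its ratio of alpha to beta globin in the other KO libraries, but the ratio differed (Cramer V up to 0.552). Alpha globin was at 46.7% of globin counts in KO library 1 and at 28.9, 32.7, 19.1 and 53.5% in KO libraries 2 to 5. Carry-over of its reads is therefore not the only source. The ratio cannot test carry-over of cells or RNA before sequencing, where small numbers of molecules could change it. Red cell RNA in the sorted KO samples and an effect of genotype remain open and untested, though the sort described, for lineage-negative and CD90.2-positive cells, selects against red cells.

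The third pattern is the absence of Maf from 4 of 5 KO libraries, which the design predicts. A model of missing genes from WT level and genomic span, which treats the KO libraries as independent, was applied. It gave a probability of 0.143 that a gene like Maf has at most 3 counts in at least 4 KO libraries. The probability was 0.00435 when missing is set at 0 counts and 0.214 at up to 10 counts. The limits of 3 and 10 counts leave room for random loss and that of 0 argues against it. Loss of molecules and deletion of the gene therefore cannot be told apart by these limits. The 108 counts in KO library 4 are above the background of 0 in the other KO libraries, and no test here shows whether they come from undeleted cells, from exons outside the deleted part or from another library.

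For the 8 gene lists that passed, 2 of 100 splits gave as many, the real one included, which is under the limit of 0.05 set for chance. The highest other split gave 9, more than the real one, so the number of lists alone is weak evidence. That other split placed 4 WT libraries with 1 KO library.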

How the results depend on the processing

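Thinning, leaving out globin and mitochondrial genes, the genes of at least 100 CPM, leaving out KO libraries 1 and 5 and the permutation tests were chosen after seeing the data. No paired analysis was possible because the replicate numbers are in the order of deposit and pair nothing. The sex covariate was not run, since both sexes were not seen in both groups. Lower calls (2027 in the main test) stayed within 1.5 times under all settings except the following. Guessed blocks of related animals, each within 1 genotype, with a random effect gave 3119. The consensus correlation of these blocks was −0.205, and a negative value narrows the error of a contrast between blocks. Thinning gave 1274, leaving out KO libraries 1 and 5 gave 3291, and genes of at least 100 CPM gave 1. Leaving out a single KO library also moved the count, except for KO library 1 (3021). Over all libraries left out in turn there were 1734 to 3350, and 1639 of the 2027 were kept in all 10 such fits. Higher calls (112) were 193 with RLE size factors, 49 with library size alone, 1483 with DESeq2, 71 with voom, 2345 with no low-count filter, 205 with 1 surrogate variable, which is mostly KO library 1, 50 after thinning, 348 without KO libraries 1 and 5, 11 among genes of at least 100 CPM, 40 and 224 at adjusted p under 0.01 and 0.1, and 82 to 333 with 1 library left out; 40 of the 112 were kept in all 10. Gene lists called (8) were 2 with library size alone, 5 with DESeq2, 5 with no low-count filter, 5 with the random effect, 1 among genes of at least 100 CPM, 0 with an estimated correlation and 18 with fry. The limit of 100 CPM is set on the mean of both groups, so it removes genes absent from KO and keeps genes absent from WT, and its counts say nothing on the balance of calls. The cause of the other changes was not tested. The log2 fold change of Maf kept its sign and passed with DESeq2 (−4.22, adjusted p = 0.0498), voom (−7.23), voom with weights (−7.10) and the random effect (−7.12); leaving out 1 library gave −13.61 to −4.02, the former without KO library 4. Over the alternatives its adjusted p ran from 0.00129 to 0.22.

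Of the 96 other named genes tested and reported, 70 passed and 0 of these changed sign under any setting run. Where they were tested, 66 of the 70 passed in all 10 fits that left out 1 library and 55 passed in every setting; 29 of the 96 were tested at 100 CPM, 72 after thinning and 16 by permutation. Otud1, Sox5, Atf3 and Ccr7 lost their calls in both kinds of setting (adjusted p up to 0.286, 0.234, 0.272 and 0.203). Lost in other settings alone were Btla (up to 0.0998), Il1rap (0.0737), Bcl6 (0.0686), Lyz2 (0.153), Chil3 (0.429), Xcr1 (0.0502), Uqcrb (0.0534), Hist1h1d (0.089) and Hist1h2bc (0.0569), and in the permutation test, at the smallest p it allows, Il4 and Mafk (0.0582 each). Of the 26 that did not pass, 16 passed in some setting with their sign kept. Among them were Il5, Il13, Trbc2 and H2-Aa with voom, where the median tested gene stood at −3.58. Rora, Il1rl1, Thy1, Il6, Ccl1, Rps14, Rpl27 and mt-Nd2 passed with DESeq2. The median there was 1.24, over all genes with any count, a wider set than the genes tested with voom. Mafg, Gfi1 and H2-Eb1 passed with their sign reversed when 1 KO library was left out (edgeR adjusted p = 0.00598, 0.017 and 0.0106). H2-Eb1 also passed with its sign reversed in an alternative that kept all libraries. Sign changes, all of genes that did not pass, were as follows. With library size alone: Areg −0.80, Gata3 −0.12, Il7r −0.40, Icos −1.52, Mafg −0.9995, Cd74 −0.013 and H2-Eb1 −0.506. With voom: Areg −1.22, Icos −0.58, Mafg −3.83, Cd74 −0.598, Gfi1 −1.86 and H2-Eb1 −4.98. With voom and sample weights: Areg −1.92, Icos −0.44, Mafg −3.99, Thy1 −0.18, Cd74 −0.685, Gfi1 −2.405 and H2-Eb1 −5.10. With the random effect: Areg −0.89, Icos −0.78, Mafg −4.29, Cd74 −0.27, Gfi1 −1.63 and H2-Eb1 −4.85. As differences of mean log2(CPM + 1): Areg −1.39, Icos −0.40 and Mafg −1.92. Without KO libraries 1 and 5: Gata3 −0.30, Icos −0.57 and Il17rb 0.422. With RLE size factors Klrg1 was 0.58, Maff 1.02 and Il17rb 0.193, and with DESeq2 0.48, 0.91 and 0.104. With 1 surrogate variable Klrg1 was 0.064, Icos −1.34 and Il17rb 0.262, and after thinning Klrg1 was 0.084 and Mafg −0.34. With no low-count filter Mafg was −0.16, and the lists of receptors and of immediate-early genes pointed down, at adjusted p = 0.84 and 0.723. Leaving out 1 library gave −1.25 to 0.74 for Areg, −10.66 to 0.53 for Mafg, −0.83 to 1.73 for Icos, −2.62 to 0.40 for Klrg1, −0.137 to 1.61 for Cd74, −5.19 to 3.46 for Gfi1, −7.54 to 1.07 for H2-Eb1 and −5.69 to 0.72 for Il17rb. The cause of these sign changes was not tested.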

Other observations

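The tests in this part were chosen after the results were seen, and the limit of 10 counts was the third tried, after limits of 3 and 0. They ask which genes stand out against the general loss from the KO libraries. A model of how often a gene of a given WT level and genomic span is missing from each KO library gives an exact one-sided tail probability, with the KO libraries taken as independent, and was fitted over the 4538 genes of at least 20 CPM in WT (per library size). With missing set at up to 3 counts, 1 gene was missing more often than the model allows after adjustment: Chil3, the macrophage chitinase-like protein Ym1 (adjusted p = 0.00757). Chil3 had 16, 5954, 5168, 58165 and 9 counts in WT libraries 1 to 5, so its WT mean rests on 3 libraries. In the other 2 WT libraries it was low as well, though above 3 counts. With missing set at up to 10 counts, 2 genes passed, Chil3 (adjusted p = 0.00206) and Irf4. Irf4 was even among the WT libraries, with 6738 to 13632 counts, and had 0, 1, 4, 3 and 4 counts in KO libraries 1 to 5.

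A hypothesis is therefore that Irf4 RNA fell in c-Maf KO ILC2 beyond the loss that the KO libraries share. The model gave Irf4 an exact tail probability with an adjusted p = 0.0409 with missing set at up to 10 counts, where 0.884 missing libraries were expected and 5 seen, but at up to 3 counts it was missing in 3 KO libraries with an exact tail p = 0.0033, which does not pass the adjustment over all genes. The adjusted value holds for 1 of the 3 limits tried and is not adjusted for that choice, and independence of the KO libraries did not hold over all genes (615 missing in all 5, 527 expected), so random loss of molecules is not excluded. Celf1, an RNA-binding protein, came next with at most 3 counts in 5 of 5 KO libraries (exact tail p = 0.000707, which does not pass the adjustment). With missing set at 0 counts, the smallest exact tail p was that of H2-Ab1 (0.000286), and Maf had 0.00435. At that setting 0 of 4538 genes passed the adjustment and 100 had an unadjusted p under 0.05, fewer than the 227 that are 5% of the genes.

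In KO library 1, 38.3% of counts fell on the locus CT010467.1 and 6.06% on Gphn, against 0.66 to 1.74% and 0.441 to 0.831% in the WT libraries. The share of counts on mitochondrially encoded genes, ribosomal RNA included, was 38.51 ± 5.47% in WT and 25.03 ± 9.39% in KO (SD, n = 5 each). Most of it was mitochondrial ribosomal RNA, at 30.08 to 42.53% of counts in WT and 9.079 to 31.71% in KO. The gene list of mitochondrially encoded genes holds no ribosomal RNA, so this share does not bear on that list. Across 7544 protein-coding genes with under 25 WT counts, which are not independent replicates, KO counts rose with genomic span (Spearman rho 0.55), as WT counts did in the same genes (rho 0.36), and the partial correlation was 0.454 for span given exonic length and 0.00257 for exonic length given span.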
